A study of Homo sapiens with 10 samples.

How the data were processed

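RNA was profiled in U937 cells, a human monocytic line, that had been differentiated with interferon gamma. There were 10 arrays in 5 groups of 2: cells with no cross-linking listed (control), cells cross-linked through the low-affinity IgG receptor CD32 for 2 h or 6 h, and cells cross-linked through the high-affinity IgG receptor CD64 for 2 h or 6 h. The labels gave the control no time. The second array of each cross-linked group was labelled a duplicate without saying whether it came from a separate culture, so every p-value measures only the spread between these arrays. One CD32 2 h array had a source name that read otherwise, and its title and description, which said CD32, were followed.

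The deposited values were linear signal intensity, 1 value per probe set and array, from a 1-colour oligonucleotide array. The submitters had scaled them: the mean signal without the lowest and highest 2% of probe sets was 500.5 to 500.6 on each of the 10 arrays. The software behind that scaling was not given in the sources used here. The table held 8793 probe sets, of which 47 were control probe sets. Gene symbols came from the reference annotation: of the 8746 other probe sets 7840 had 1 symbol, 388 had several and 518 had none. The array number limits the precision of each value.

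The rules for scaling, the floor, the tests, the gene lists and the genes to be named were fixed before the data were examined. Because the trimmed means were alike, the values were used as deposited. Values under a floor of 37.5, the percentile 25 of all values, were set to the floor and log2 was taken. Probe sets above the floor on at least 2 arrays were tested, which left 7708 probe sets, 6925 of them with 1 symbol, for 6814 genes. A linear model with 1 term per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the mean signal), which left 5 residual degrees of freedom beside a prior of 5.65 and gave a median standard deviation of 0.286 on the log2 scale. Tests were two-sided, and p-values were adjusted over all probe sets tested by the method of Benjamini and Hochberg. A change was called at an adjusted p under 0.05. The comparisons were each cross-linked group against control, CD64 against CD32 at each time, 6 h against 2 h of each receptor, and the interaction of receptor and time. Errors are standard errors of the log2 difference from limma unless called SD, with 2 arrays per group throughout. Where the mean signal of the lower group of a comparison lay at or under the floor, the fold is given as a lower bound. Where 1 array of that group lay under the floor and the mean above it, the fold is the fitted value with that array set to the floor and is no bound.

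The 32 gene lists held 841 genes, 660 of them on the array. They covered inflammatory cytokines and chemokines, NF-kappaB targets and feedback regulators, immediate early transcription factors and phosphatases, interferon-stimulated genes, MHC class II and its assembly, Fc receptors and their proximal signalling, NADPH oxidase, lysosome and cathepsins, proteasome, cholesterol synthesis and uptake, liver X receptor targets and lipid handling, and glycolysis and hypoxia response. Further lists covered mitotic and G2/M genes, DNA replication and S phase genes, cyclin-dependent kinase inhibitors and p53 targets, heat shock and chaperones, the unfolded protein response and amino acid stress, oxidative stress and NRF2 targets, metallothioneins, apoptosis regulators of the BCL2 and IAP families, matrix proteases with coagulation and tissue remodelling, and macrophage differentiation markers. The last lists covered immature myeloid and primary granule genes, histones, cytoplasmic ribosomal proteins, ribosome biogenesis and nucleolus, oxidative phosphorylation, and markers of T cells, of B cells and plasma cells, of natural killer cells, of erythroid cells and platelets, and of epithelial cells and fibroblasts. Each gene entered its list once, through its probe set with the highest mean. A list was tested with camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, and p-values were adjusted over the 32 lists of a comparison. Camera compares a list with the other genes. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Members of a list were also counted with p-values adjusted over the list alone.

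The genes to be named were chosen by a fixed rule. Against control it took, among called probe sets with 1 symbol whose arrays did not overlap with the control arrays, the 8 genes with the highest and the 8 with the lowest log2 change, up to 3 called members of each list with the largest change, and the Fc gamma receptor genes. For the other comparisons it took the 5 highest, the 5 lowest and up to 2 called members per list. The rule gave 256 distinct genes, and 1 further gene was left out because it lies on chromosome Y.

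The overlap between the CD32 and CD64 comparisons was set beside 100 simulations of unchanged groups that shared the same 2 controls. The method was tested on simulated data with 200 changed probe sets of 7708 in 20 runs. It recovered 15.6% of changes of 1.5-fold, 36.8% of changes of 2-fold and 67.3% of changes of 4-fold, with 4.04% false calls and a mean of 0.05 calls in an unchanged comparison. Fewer probe sets changed there than were called in the comparisons with control, and no difference between arrays went with the group. These rates need not hold for the data. One list shifted by 0.5 log2 units was found, and 0 of the other lists were called by camera.

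Counts and named genes were recomputed under alternatives fixed in advance: quantile normalization, no floor, a floor of double the value, no filter, no variance trend, only the groups compared, a term for the duplicate arrays, 1 probe set per gene, and leaving out each array in turn, where the array left alone in its group was assumed to vary like the other groups. The gene lists were recomputed under the same alternatives except only the groups compared and 1 probe set per gene. Alternatives chosen after seeing the data were cyclic loess normalization, leaving out the brightest 5% of probe sets, leaving out both CD64 6 h arrays or both CD32 6 h arrays, and, for the calls shared by the receptors, setting each receptor against its own single control array. Control probe sets were left out of the tests and used to describe the arrays: bacterial transcripts of the kind added to every sample before hybridisation, the ratio of 3' to 5' probe sets of actin, and 28S ribosomal RNA.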

Results

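Gene expression was measured in U937 cells, a human monocytic line, after differentiation with interferon gamma and cross-linking of an Fc gamma receptor, a receptor for the constant part of IgG antibodies. CD32, the low-affinity receptor, or CD64, the high-affinity receptor, was cross-linked for 2 h or 6 h, and the control cells had no cross-linking listed. Each of the 5 groups had 2 arrays, 10 in all. The labels do not say whether the duplicates were separate cultures, so the p-values measure only the spread between these arrays. The comparisons ask how each receptor changed expression, how the receptors differed and how the changes developed between 2 h and 6 h. The median signal per array lay between 101 and 153, and between 20.2% and 29.8% of probe sets lay at or under the floor of 37.5. The array number limits the precision.

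The cross-linked groups stood apart from the controls and from each other. Principal components 1 and 2 held 25.3% and 19.6% of the variance, and for 10 of 10 arrays the most correlated partner was the other array of its group. Correlations were 0.9639 to 0.9771 within groups and 0.9248 to 0.9707 between groups, across probe sets, which are not independent replicates. The 2 control arrays, which all comparisons with control share, were the least alike pair of a group, at 0.9639. On component 3, which held 15.9% of the variance, they lay at 19.51 and -14.41. In the limma F-test over the 4 comparisons with control, 2657 of 7708 probe sets changed, or 34.5%. In 4 of 4 comparisons, 224 probe sets rose and 124 fell. The groups also differed in control probe sets. The 9 probe sets for added bacterial transcripts, with the bacteriophage gene cre counted among them, had a median SD within pairs of 0.101 log2 units. Their SD between group means was 1.08, and on them the CD32 6 h arrays read 4.14-fold to 11.6-fold above the CD64 6 h arrays. The mean log2 signal of these probe sets was 10.88 in control, 11.48 in CD32 2 h, 12.61 in CD32 6 h, 11.18 in CD64 2 h and 9.61 in CD64 6 h. The ratio of 3' to 5' actin signal was 1.31, 1.56, 1.99, 1.81 and 1.12 in the same order. Because these measures went with the group, differences in labelling or hybridisation cannot be told apart from the group. Residuals of the duplicate arrays correlated between groups, across probe sets, at -0.0594 to 0.285 over 6 pairs of groups, with a median of 0.0137.

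**Figure D1:**
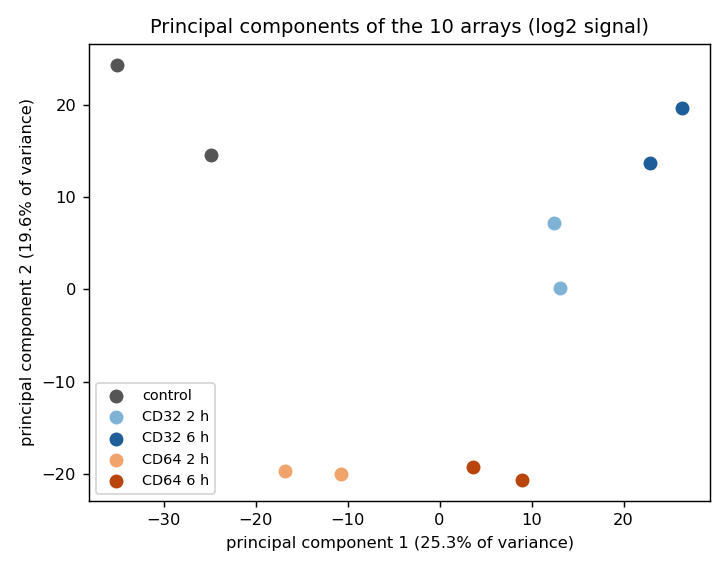
Principal components 1 and 2 of the log2 signal of the 7708 tested probe sets, with 1 point per array and colours for the 5 groups. The components hold 25.3% and 19.6% of the variance. Of the pairs of a group the 2 control arrays lie farthest apart, at -35.06 and -24.82 on component 1 and at 24.3 and 14.53 on component 2.

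After 2 h of CD32 cross-linking, the cell cycle inhibitor CDKN1A rose from a mean signal of 26.8 ± 14.5 (SD, n = 2) in control to 392 ± 97.6, at least 10.3-fold (log2 3.36 ± 0.274 SE, adjusted p = 1.99e-05, limma). The monocyte chemokine CCL2 rose 5.97-fold (2.58 ± 0.155), the hyaluronan-binding protein TNFAIP6 rose 7.04-fold (2.82 ± 0.341), TXNIP, a thioredoxin inhibitor, rose 7.1-fold (2.83 ± 0.0939), and the fractalkine receptor CX3CR1 rose 5.97-fold (2.58 ± 0.246). For TNFAIP6 1 control array lay under the floor (78.1 and 6.5), so its fold depends on the floor. The transcription factor MYC fell 4.17-fold (-2.06 ± 0.143), and the hypoxia-responsive genes HILPDA and HK2, a hexokinase, fell 5.31-fold and 4.34-fold. In all, 1192 of 7708 probe sets changed, 683 upward and 509 downward, and 421 changed by more than 2-fold.

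The unfolded protein response and amino acid stress list rose: 13 of 24 genes rose and 0 fell, both over all genes and adjusted over the list alone (camera adjusted p = 4.05e-08, and 0.0435 with an estimated correlation). Among them the pseudokinase TRIB3 rose 5.21-fold, the cystine transporter SLC7A11 4.68-fold and the chaperone DNAJB9 3.81-fold. Of 47 interferon-stimulated genes 18 rose and 3 fell, with 22 and 4 adjusted over the list alone (adjusted p = 0.000124, and 0.0435 with an estimated correlation); ISG15 rose 3.28-fold and OAS2 2.93-fold. Mitotic genes fell, 14 of 31 with 0 rising, or 18 adjusted over the list alone (adjusted p = 7.15e-08, and 0.0435 with an estimated correlation), among them the topoisomerase TOP2A by 2.25-fold and the kinase CDK1 by 1.95-fold. Of 25 glycolysis and hypoxia genes 2 rose and 10 fell, with 2 and 14 adjusted over the list alone (adjusted p = 9.86e-06, and 0.0435 with an estimated correlation). Other lists were called at the preset correlation only. Of 19 NF-kappaB targets 9 rose and 1 fell, with 11 and 2 adjusted over the list alone (adjusted p = 0.000361, and adjusted p = 0.269 with an estimated correlation); the maturation marker CD83 rose 4.46-fold and IER3 3.24-fold. Of 12 MHC class II genes 5 rose and 0 fell (adjusted p = 0.00357, and adjusted p = 0.0956 with an estimated correlation), with the antigen-presenting chain HLA-DRA up 2.29-fold. Of 18 cholesterol genes 1 rose and 6 fell, with 1 and 11 adjusted over the list alone (adjusted p = 0.00078, and adjusted p = 0.0756 with an estimated correlation), with the synthase HMGCS1 down 2.39-fold. Of 41 oxidative phosphorylation genes 1 rose and 11 fell, with 1 and 14 adjusted over the list alone (adjusted p = 3.87e-05, and adjusted p = 0.145 with an estimated correlation). The macrophage marker and ribosomal protein lists were called at that correlation too. At an unadjusted p under 0.05 by limma 8 of 23 and 0 of 46 genes of these were higher, and 2 and 7 lower. Each of these list calls was lost without 1 or more single arrays. Immediate early genes went both ways, 10 of 29 up and 5 down (adjusted p = 0.0639), with the phosphatase DUSP5 up 4.15-fold and the transcription factor ATF3 up 3.65-fold. The count of 1192 dropped to 579 without CD32 2 h replicate 1 and to 592 without CD32 2 h replicate 2.

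After 6 h of CD32 cross-linking, CDKN1A reached a signal of 1111 ± 29.8 (SD, n = 2), at least 29.6-fold above control (log2 4.89 ± 0.274 SE, adjusted p = 1.47e-06). The AP-1 transcription factor FOSB rose at least 16.8-fold (4.07 ± 0.352) and the zinc finger transcription factor EGR1 rose 15.2-fold (3.92 ± 0.313). CCL2 rose 11.1-fold, IER3 10.1-fold and the collagenase MMP1 9.42-fold. The transcription factors SOX4 and MYC fell 6.26-fold and 5.69-fold, HILPDA fell 5.59-fold, and the chaperone HSP90AA1 fell 3.6-fold. In all, 1539 probe sets changed, 742 upward and 797 downward, and 623 changed by more than 2-fold. Of all calls 48.2% were upward, or 54.8% under cyclic loess normalization, which was chosen after seeing the data.

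Of 47 interferon-stimulated genes 27 rose and 1 fell after 6 h of CD32, with 29 and 1 adjusted over the list alone (camera adjusted p = 5.76e-13, and 0.0104 with an estimated correlation); IFI44L rose at least 7.95-fold and ISG15 6.07-fold. Of 29 immediate early genes 16 rose and 3 fell, with 17 and 3 adjusted over the list alone (adjusted p = 1.06e-07, and 0.0494 with an estimated correlation), with ATF3 up 7.05-fold. Of 12 MHC class II genes 5 rose and 0 fell, with 6 adjusted over the list alone (adjusted p = 0.000106, and 0.0494 with an estimated correlation); the invariant chain CD74 rose 2.57-fold and HLA-DMA, which helps load peptides, 2.52-fold. Mitotic genes fell, 19 of 31 with 0 rising, or 22 adjusted over the list alone (adjusted p = 5.54e-08, and 0.0494 with an estimated correlation), with the checkpoint gene MAD2L1 down 2.04-fold. Other lists were called at the preset correlation only. Of 23 cytokine and chemokine genes 8 rose and 0 fell, with 9 adjusted over the list alone (adjusted p = 0.000128, and adjusted p = 0.0529 with an estimated correlation), with the neutrophil chemokine CXCL8 up 5.69-fold. Of 19 NF-kappaB targets 10 rose and 0 fell, with 11 adjusted over the list alone (adjusted p = 1.5e-07, and adjusted p = 0.105 with an estimated correlation), with CD83 up 7.26-fold. Of 33 DNA replication genes 3 rose and 14 fell, with 3 and 15 adjusted over the list alone (adjusted p = 0.000149, and adjusted p = 0.0595 with an estimated correlation); the clamp loader subunit RFC5 fell 2.9-fold and the phosphatase CDC25A rose 3.68-fold. Of 24 unfolded protein response genes 11 rose and 2 fell, with 13 and 3 adjusted over the list alone (adjusted p = 0.000215, and adjusted p = 0.0529 with an estimated correlation). Of 23 macrophage markers 7 rose and 1 fell, with 9 and 1 adjusted over the list alone (adjusted p = 0.00154, and adjusted p = 0.0529 with an estimated correlation), with the calgranulin S100A8 up 2.14-fold. The ribosomal protein, oxidative phosphorylation and matrix and coagulation lists were called at that correlation too. At an unadjusted p under 0.05 by limma 18 of 46, 2 of 41 and 6 of 22 genes of these were higher. In the same order 6, 16 and 2 were lower. Each of these list calls was lost without 1 or more single arrays. Camera did not call the glycolysis list (adjusted p = 0.489), although the pyruvate kinase PKM rose 2.83-fold and HK2 fell 2.48-fold. Of its 25 genes 3 were higher and 8 lower at an unadjusted p under 0.05 by limma. These arrays had the highest bacterial transcript signal, 1.72 log2 units above control, and an actin ratio of 1.99 against 1.31 in control. The count of 1539 dropped to 942 without CD32 6 h replicate 1.

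After 2 h of CD64 cross-linking, CXCL8 rose from 174 ± 33.2 (SD, n = 2) to 2402 ± 77.1, or 13.9-fold (log2 3.80 ± 0.145 SE, adjusted p = 1.35e-07), and the related chemokine CXCL2 rose 8.43-fold (3.08 ± 0.402). For CXCL2 1 control array lay under the floor (19.3 and 58.3), so its fold depends on the floor. CCL2 rose 5.21-fold, the haem-degrading enzyme HMOX1 4.13-fold, the survival factor MCL1 2.81-fold and CDC25A 6.33-fold. The NF-kappaB subunit NFKB2 fell 4.86-fold, the cholesterol synthesis enzyme MVD 4.83-fold, the transcription factor KLF6 3.21-fold, and the primary granule genes AZU1 and PRTN3 fell 3.49-fold and 3.07-fold. In all, 1224 probe sets changed, 589 upward and 635 downward, and 381 changed by more than 2-fold. Upward calls made up 48.1%, or 52.3% under quantile and 53.3% under cyclic loess normalization. The median of all 7708 log2 changes was -0.13 as deposited and 0 under quantile normalization.

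Cholesterol genes fell after 2 h of CD64, 11 of 18 with 0 rising, or 12 adjusted over the list alone (camera adjusted p = 8.38e-06, and adjusted p = 0.102 with an estimated correlation); MSMO1 fell 2.13-fold and LSS 1.8-fold, both enzymes of sterol synthesis. Of 25 glycolysis and hypoxia genes 1 rose and 12 fell, with 2 and 14 adjusted over the list alone (adjusted p = 0.000978, and adjusted p = 0.106 with an estimated correlation), with HILPDA down 3.58-fold and the glucose transporter SLC2A3 down 2.79-fold. Of 47 interferon-stimulated genes limma called 0 higher and 10 lower, with 0 and 12 adjusted over the list alone and 1 and 23 at an unadjusted p under 0.05 (camera adjusted p = 0.00501, and adjusted p = 0.112 with an estimated correlation), and the interferon regulatory factors IRF1 and IRF7 fell 2.04-fold and 1.98-fold. Of 18 oxidative stress genes 7 rose and 2 fell, with 8 and 2 adjusted over the list alone (adjusted p = 0.00613, and adjusted p = 0.13 with an estimated correlation), with SQSTM1, an autophagy receptor, up 2.18-fold. Of 5 metallothioneins 3 rose (adjusted p = 0.0164, and adjusted p = 0.174 with an estimated correlation); that call was lost without control replicate 2 (adjusted p = 0.0576) and without CD64 2 h replicate 2 (adjusted p = 0.0543). Camera did not call the mitotic list (3 of 31 up, 2 down, adjusted p = 0.303), with a median log2 change of 0.05 as deposited and -0.01 under quantile normalization. Immediate early genes were not called as a list by camera (8 of 29 up, 2 down, adjusted p = 0.111). At the preset correlation camera called 8 of 32 lists, among them the unfolded protein response, ribosomal protein and oxidative phosphorylation lists. At an unadjusted p under 0.05 by limma 9 of 24, 2 of 46 and 14 of 41 genes of these were higher. In the same order 4, 1 and 6 were lower. Each of these list calls was lost without control replicate 1 and without CD64 2 h replicate 2. With an estimated correlation camera called 0 of 32 lists, while 6 had an unadjusted p under 0.05 and fry called 14. The call of the interferon list was lost without the brightest 5% of probe sets (adjusted p = 0.0558). The count of 1224 dropped to 741 without control replicate 1, to 642 without CD64 2 h replicate 1 and to 711 without CD64 2 h replicate 2. It dropped to 725 without the variance trend and to 767 with only the groups compared.

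After 6 h of CD64 cross-linking, CCL2 rose from 152 ± 6.01 (SD, n = 2) to 6955 ± 383, or 45.8-fold (log2 5.52 ± 0.155 SE, adjusted p = 1.53e-08). TNFAIP6 rose 22.2-fold (4.47 ± 0.341), and the antiviral genes IFIT3 and IFIT1 rose 18.7-fold (4.22 ± 0.214) and 17.5-fold (4.13 ± 0.186). The chemokine CCL4 rose 16.4-fold, ISG15 12.7-fold, the interleukin-1 receptor antagonist IL1RN 10.1-fold, the myeloid receptor TREM1 8.78-fold, MMP1 8.73-fold and the cyclin CCNE2 6.89-fold. For CCL4 (145 and 6.7), TNFAIP6 (78.1 and 6.5) and TREM1 (67.2 and 27.2) 1 control array lay under the floor, so these folds depend on the floor. HILPDA fell 6.21-fold, HK2 4.05-fold and the progenitor transcription factor MYB 2.87-fold. In all, 1591 probe sets changed, 825 upward and 766 downward, and 603 changed by more than 2-fold.

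Of 47 interferon-stimulated genes 25 rose and 3 fell after 6 h of CD64, with 29 and 3 adjusted over the list alone (camera adjusted p = 1.1e-11, and 0.0075 with an estimated correlation). Glycolysis and hypoxia genes fell, 19 of 25 with 1 rising, or 20 and 1 adjusted over the list alone (adjusted p = 6.68e-12, and 0.0075 with an estimated correlation). Cholesterol genes fell, 11 of 18 with 0 rising, or 12 and 1 adjusted over the list alone (adjusted p = 5.75e-06, and 0.0335 with an estimated correlation), with LSS down 2.35-fold and the isomerase IDI1 down 2.32-fold. Mitotic genes fell, 14 of 31 with 0 rising, or 20 adjusted over the list alone (adjusted p = 3.56e-09, and 0.0335 with an estimated correlation), with TOP2A down 2.16-fold and the checkpoint kinase BUB1 down 2.1-fold. Of 46 ribosomal protein genes 38 fell as deposited, or 43 adjusted over the list alone, with a median log2 change of -0.61 (adjusted p = 1.95e-20, and adjusted p = 0.11 with an estimated correlation), whereas under quantile normalization 0 fell, 1 rose and the adjusted p was 0.958. The CD64 6 h arrays had the lowest bacterial transcript signal, 9.61 against 10.88 in control, and a highest signal of 15202 against 28012, and their 28S ribosomal RNA probe set read 4146 against 742. Of 14 immature myeloid genes 7 fell and 0 rose (adjusted p = 0.000583, and adjusted p = 0.0607 with an estimated correlation), with AZU1 down 2.7-fold and PRTN3 2.31-fold. Of 24 unfolded protein response genes 12 rose and 3 fell, with 13 and 4 adjusted over the list alone (adjusted p = 0.000489, and adjusted p = 0.0607 with an estimated correlation), with SLC7A11 up 5.13-fold and TRIB3 4.33-fold. Of 23 cytokine genes 7 rose and 0 fell, with 7 and 2 adjusted over the list alone (adjusted p = 0.00541, and adjusted p = 0.108 with an estimated correlation). Of 19 NF-kappaB targets 8 rose and 1 fell, with 10 and 2 adjusted over the list alone (adjusted p = 0.00093, and adjusted p = 0.282 with an estimated correlation), with CD83 up 4.38-fold. Of 12 MHC class II genes 4 rose and 1 fell, with 5 and 1 adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.108 with an estimated correlation), with HLA-DRA up 3.27-fold. Of 26 proteasome genes 7 rose and 0 fell, with 8 adjusted over the list alone (adjusted p = 0.0282, and adjusted p = 0.288 with an estimated correlation); that call was lost without control replicate 1 (adjusted p = 0.276) and without CD64 6 h replicate 2 (adjusted p = 0.11). The count of 1591 dropped to 967 without CD64 6 h replicate 1 and to 1023 without CD64 6 h replicate 2.

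**Figure D2:**
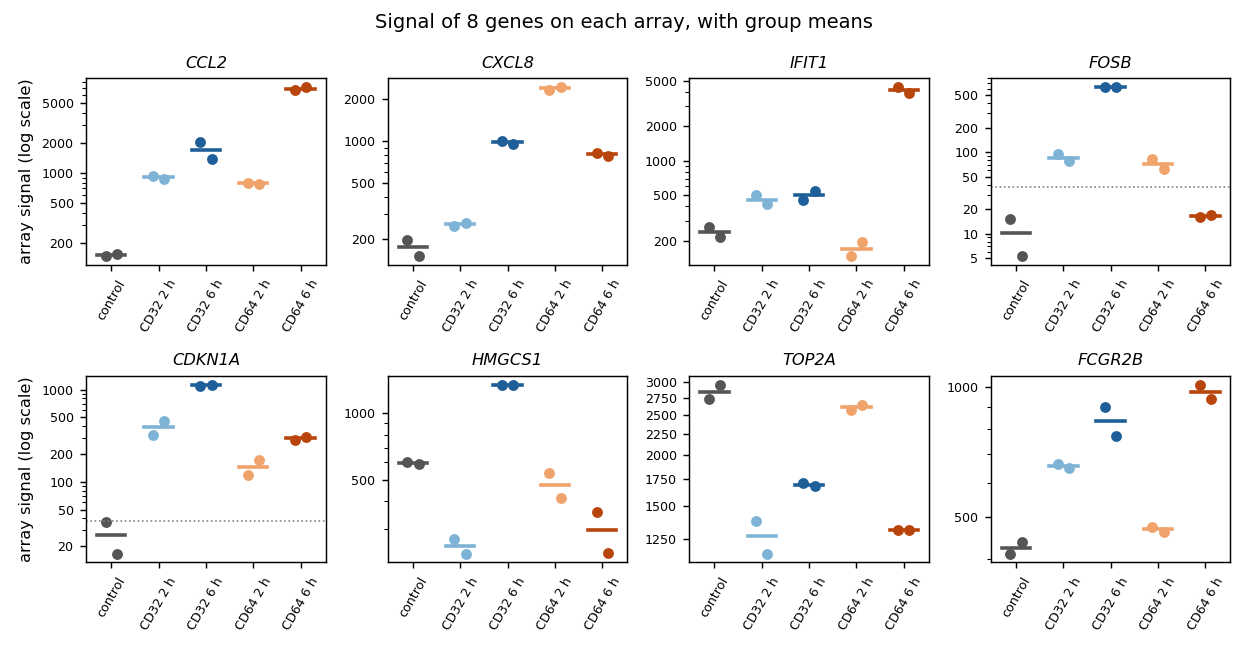
Signal of 8 genes on each array, on a log axis, with 1 point per array, lines at the 5 group means and a dotted line at the floor of 37.5 where a gene reaches it. CCL2 reaches 6955 after 6 h of CD64, CXCL8 is highest at 2402 after 2 h of CD64, and FOSB is highest at 629 after 6 h of CD32.

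**Figure D3:**
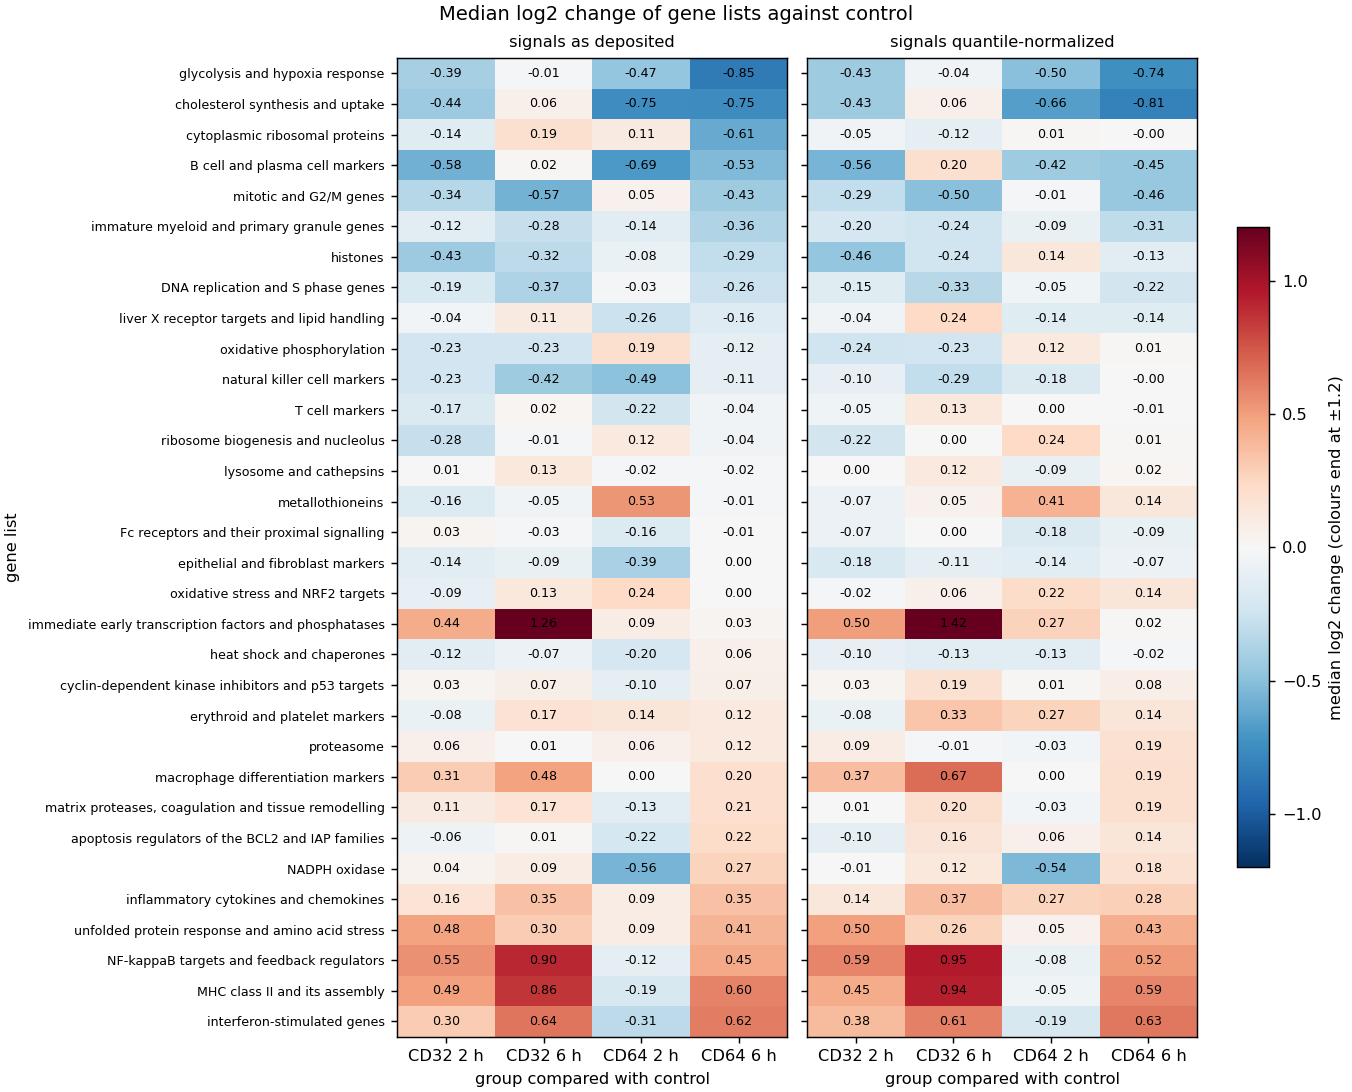
Median log2 change of the measured genes of each of the 32 lists in the 4 comparisons with control, as deposited and under quantile normalization, with colour for the size and direction. The ribosomal protein list after 6 h of CD64 is at -0.61 as deposited and at -0.00133 under quantile normalization, and the interferon list is at 0.62 as deposited.

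Against the same 2 control arrays, CD32 and CD64 shared much of their change. The labels gave these controls no time, and a difference common to both controls would also appear as shared change. Setting each receptor against its own control array does not remove such a difference. At 2 h, 518 probe sets were called the same way by both receptors, 315 up and 203 down, where 52.2 and 41.9 would be called if the calls were independent, and 37 were called in opposite directions. At 6 h, 766 were called the same way, 444 up and 322 down, against 79.4 and 79.2, and 74 in opposite directions. CCL2, SFPQ, DNAJA1, TNFRSF10B, SLC7A11 and SQSTM1 rose in 4 of 4 comparisons with control, and HILPDA and MYB fell in 4 of 4. With each receptor set against its own single control array, which was chosen after seeing the data, 257 and 290 were called the same way at 2 h in the 2 assignments, against 42.6 and 52 if the calls were independent. At 6 h 490 and 493 were, against 107 and 89.9. The log2 changes then correlated at 0.235 and 0.217 at 2 h and at 0.282 and 0.364 at 6 h. Unchanged groups were also simulated against the shared controls: 0.03 probe sets on average were called the same way at 2 h and 0 at 6 h. Almost nothing can be called in unchanged groups, so these counts do not show how far shared controls add to the overlap of real calls. Against the shared controls the log2 changes correlated across probe sets, which are not independent replicates, at 0.554 at 2 h and 0.594 at 6 h, while the simulations gave 0.499 and 0.501. The covariance exceeded the simulated one by 0.13 at 2 h and 0.201 at 6 h. The count of 518 dropped to 336 without control replicate 1, to 270 and 293 without CD32 2 h replicate 1 and CD32 2 h replicate 2, and to 311 and 344 without CD64 2 h replicate 1 and CD64 2 h replicate 2. It dropped to 289 without the variance trend and to 335 with only the groups compared.

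Compared directly at 2 h, CXCL8 was 9.44-fold higher after CD64 than after CD32 (log2 3.24 ± 0.145 SE, n = 2 per group, limma adjusted p = 2.14e-06) and CXCL2 was 6.73-fold higher (2.75 ± 0.402). The selenophosphate synthetase SEPHS2 was 4.07-fold higher, MYC 2.71-fold and the chaperone HSPH1 2.28-fold. CX3CR1 was 5.7-fold lower (-2.51 ± 0.246) and TNFAIP6 5.42-fold lower (-2.44 ± 0.341). Interferon-stimulated genes were lower after CD64, 28 of 47 with 4 higher, or 30 and 4 adjusted over the list alone (camera adjusted p = 8.19e-10, and 0.0232 with an estimated correlation), with OAS2 4.11-fold lower and the death ligand TNFSF10 3.32-fold lower. Mitotic genes were higher after CD64, 18 of 31 with 0 lower, or 18 and 2 adjusted over the list alone (adjusted p = 7.37e-11, and 0.0427 with an estimated correlation), with CDK1 2.1-fold higher. Of 41 oxidative phosphorylation genes 20 were higher and 0 lower, or 23 and 0 adjusted over the list alone (adjusted p = 5.38e-11, and adjusted p = 0.0672 with an estimated correlation), with NDUFB5 1.71-fold higher. Of 24 unfolded protein response genes 1 was higher and 11 lower, or 2 and 14 adjusted over the list alone (adjusted p = 0.00013, and adjusted p = 0.0672 with an estimated correlation), with the serine synthesis enzyme PSAT1 3.01-fold lower and TRIB3 2.87-fold lower. Of 19 NF-kappaB targets 1 was higher and 9 lower, or 1 and 11 adjusted over the list alone (adjusted p = 4.97e-05, and adjusted p = 0.198 with an estimated correlation). Of 12 MHC class II genes 5 were lower and 0 higher (adjusted p = 0.00393, and adjusted p = 0.0985 with an estimated correlation), with CD74 3.16-fold lower and HLA-DPB1 3.11-fold lower. Of 33 DNA replication genes 10 were higher and 1 lower, or 10 and 2 adjusted over the list alone (adjusted p = 0.00147, and adjusted p = 0.101 with an estimated correlation), with the ribonucleotide reductase subunit RRM2 1.88-fold higher. In all, 1256 probe sets differed, 529 higher and 727 lower after CD64. Higher calls made up 42.1%, or 48.3% under quantile and 49.2% under cyclic loess normalization, and the median of all changes was -0.11 as deposited and 0 under quantile normalization. The count dropped to 699 and 586 without CD32 2 h replicate 1 and CD32 2 h replicate 2. It dropped to 690 and 770 without CD64 2 h replicate 1 and CD64 2 h replicate 2, and to 830 without the variance trend.

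At 6 h, IFIT1 was 8.33-fold higher after CD64 than after CD32 (log2 3.06 ± 0.186 SE, n = 2 per group, adjusted p = 5.47e-06), the RNA sensor RIGI 5.05-fold, the caspase CASP6 4.84-fold, CCL2 4.13-fold, CCNE2 3.7-fold and the pentraxin PTX3 3.55-fold higher. FOSB was at least 16.8-fold lower after CD64 (-4.07 ± 0.352) and EGR1 6.73-fold lower (-2.75 ± 0.313). Immediate early genes were lower after CD64, 15 of 29 with 1 higher, or 17 and 3 adjusted over the list alone (camera adjusted p = 1.54e-07, and 0.0466 with an estimated correlation). Cholesterol genes were lower, 10 of 18 with 0 higher, or 11 adjusted over the list alone (adjusted p = 7.96e-10, and 0.0179 with an estimated correlation), with HMGCS1 4.67-fold lower and IDI1 4.23-fold lower. Glycolysis genes were lower, 12 of 25 with 0 higher, also when adjusted over the list alone (adjusted p = 7.96e-10, and 0.0179 with an estimated correlation), with PKM 5.77-fold and SLC2A3 3.09-fold lower. Camera also called the NF-kappaB, lysosome, DNA replication and immature myeloid lists, at the preset correlation only. At an unadjusted p under 0.05 by limma 2 of 19, 3 of 26, 15 of 33 and 2 of 14 genes of these were higher. In the same order 8, 10, 3 and 7 were lower. Each of these list calls was lost without 1 or more single arrays. The interferon list as a whole was not called by camera, with 12 of 47 higher and 6 lower (adjusted p = 0.761). CDKN1A was 3.75-fold lower, CD74 3.58-fold lower and IER3 3.47-fold lower after CD64. Of 46 ribosomal protein genes 36 were lower and 2 higher as deposited, with a median of -0.78 (adjusted p = 1.14e-26, and adjusted p = 0.153 with an estimated correlation), whereas under quantile normalization the median was 0.12, with 10 higher and 1 lower. In all, 1357 probe sets differed, 756 higher and 601 lower after CD64. Higher calls made up 55.7%, or 47.5% under cyclic loess normalization. These groups had the highest and the lowest bacterial transcript signal, 3 log2 units apart, and actin ratios of 1.99 and 1.12. The count dropped to 749 without CD32 6 h replicate 1 and to 646 and 705 without CD64 6 h replicate 1 and CD64 6 h replicate 2.

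Between 2 h and 6 h of CD32, FOSB rose 7.4-fold (log2 2.89 ± 0.352 SE, n = 2 per group, adjusted p = 0.00165), EGR1 6.61-fold (2.72 ± 0.313), HMGCS1 5.4-fold (2.43 ± 0.21) and CXCL8 3.86-fold (1.95 ± 0.145). IER3 rose 3.12-fold, MSMO1 2.92-fold, SLC2A3 2.57-fold, the survival factor BCL2A1 2.26-fold and the urokinase receptor PLAUR 2.06-fold. Of 29 immediate early genes 7 rose and 0 fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 6.52e-12, and 0.016 with an estimated correlation). Of 18 cholesterol genes 7 rose and 0 fell, or 10 adjusted over the list alone (adjusted p = 6.44e-12, and 0.0113 with an estimated correlation). Of 47 interferon-stimulated genes 10 rose and 0 fell, or 21 adjusted over the list alone (adjusted p = 1.48e-13, and 0.00985 with an estimated correlation). Of 25 glycolysis genes 4 rose and 0 fell, or 10 and 1 adjusted over the list alone (adjusted p = 2.92e-06, and 0.0197 with an estimated correlation). Of 23 cytokine genes 4 rose and 0 fell, or 7 adjusted over the list alone (adjusted p = 1.35e-05, and 0.0375 with an estimated correlation). DNA replication genes fell, 6 of 33 with 0 rising, or 10 and 1 adjusted over the list alone (adjusted p = 0.000503, and adjusted p = 0.0918 with an estimated correlation). Of 46 ribosomal protein genes 8 rose and 0 fell as deposited, or 26 adjusted over the list alone, with a median of 0.33 (adjusted p = 1.48e-13, and adjusted p = 0.195 with an estimated correlation), whereas the median was -0.01 under quantile normalization. In all, 344 probe sets changed, 45.6% of them upward, or 56.4% under cyclic loess normalization. The count dropped to 52 and 40 without CD32 2 h replicate 1 and CD32 2 h replicate 2, and to 74 and 130 without CD32 6 h replicate 1 and CD32 6 h replicate 2. It dropped to 54 without the variance trend and to 222 without both CD64 6 h arrays.

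Between 2 h and 6 h of CD64, IFIT1 rose 24.6-fold (log2 4.62 ± 0.186 SE, n = 2 per group, adjusted p = 3.25e-07), TNFAIP6 17-fold (4.09 ± 0.341), IFIT3 16.6-fold (4.05 ± 0.214), RIGI 12.5-fold and ISG15 11.6-fold. IL1RN rose 8.87-fold, MMP1 6.02-fold and CYBB, the catalytic subunit of the phagocyte oxidase, 3.81-fold. CXCL8 fell 2.97-fold, the heat shock gene HSPA6 4.58-fold, RRM2 2.1-fold and MCL1 2.06-fold. Of 47 interferon-stimulated genes 30 rose and 0 fell, or 32 and 1 adjusted over the list alone (camera adjusted p = 6.56e-23, and 0.00271 with an estimated correlation). Mitotic genes fell, 19 of 31 with 0 rising, or 21 adjusted over the list alone (adjusted p = 2.53e-16, and 0.014 with an estimated correlation). Of 25 glycolysis genes 1 rose and 11 fell, or 2 and 13 adjusted over the list alone (adjusted p = 3.99e-08, and 0.014 with an estimated correlation), with BNIP3 down 2.31-fold and NDRG1 2.18-fold. Of 19 NF-kappaB targets 10 rose and 0 fell, or 12 adjusted over the list alone (adjusted p = 1.33e-06, and adjusted p = 0.127 with an estimated correlation). Of 12 MHC class II genes 6 rose and 0 fell (adjusted p = 0.00013, and adjusted p = 0.0555 with an estimated correlation), with HLA-DPB1 up 4.16-fold and HLA-DRA 3.62-fold. Of 22 matrix and coagulation genes 5 rose and 0 fell, or 6 adjusted over the list alone (adjusted p = 0.00588, and adjusted p = 0.103 with an estimated correlation). As deposited, 41 of 46 ribosomal protein genes fell and 0 rose (median -0.74, adjusted p = 1.19e-37, and adjusted p = 0.0624 with an estimated correlation), whereas under quantile normalization 1 fell and 2 rose. Of 41 oxidative phosphorylation genes 12 fell and 0 rose, or 15 adjusted over the list alone (adjusted p = 1.21e-08, and adjusted p = 0.0704 with an estimated correlation); the call was lost under quantile normalization (adjusted p = 0.0748). Bacterial transcript signal fell by 1.58 log2 units between the same groups. In all, 1065 probe sets changed, 583 upward and 482 downward, and the median of all changes was 0.09 as deposited and -0.01 under quantile normalization. The count dropped to 602 and 568 without CD64 2 h replicate 1 and CD64 2 h replicate 2, to 492 and 455 without CD64 6 h replicate 1 and CD64 6 h replicate 2, and to 579 without the variance trend.

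**Figure D4:**
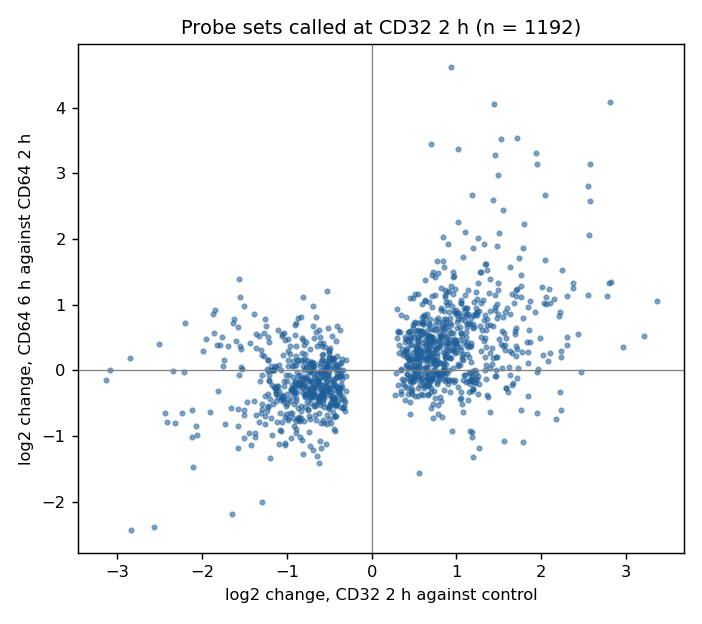
Log2 change from control to 2 h of CD32 (horizontal axis) against log2 change from 2 h to 6 h of CD64 (vertical axis), with 1 point for each of the 1192 probe sets called in the first comparison. Of these points 71.9% lie on the same side of 0 on both axes (r = 0.508, across probe sets, which are not independent replicates).

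The interaction tested whether the change from 2 h to 6 h differed between the receptors. Positive values mean that the log2 change with CD64 lay above that with CD32. This can be a larger rise or a smaller fall with CD64, or a fall with CD32. Among the called genes it was positive for IFIT1 (log2 4.49 ± 0.264 SE, n = 2 per group, adjusted p = 1.18e-05), TNFAIP6 (3.997 ± 0.483), CX3CR1 (3.70 ± 0.348), IL1RN (3.15 ± 0.217), PSAT1 (2.77 ± 0.216) and TRIB3 (1.77 ± 0.16). It was negative for CXCL8 (-3.52 ± 0.205), HMGCS1 (-3.14 ± 0.297), EGR1 (-3.01 ± 0.443) and MCL1 (-1.75 ± 0.246). Among interferon-stimulated genes, 19 of 47 had a positive and 1 a negative interaction, or 26 and 1 adjusted over the list alone (camera adjusted p = 7.38e-07, and 0.0277 with an estimated correlation). Negative interactions were found for 9 of 29 immediate early genes, or 14 adjusted over the list alone (adjusted p = 9.1e-07, and 0.0379 with an estimated correlation). The same held for 11 of 25 glycolysis genes, or 12 adjusted over the list alone (adjusted p = 4.43e-12, and 0.0145 with an estimated correlation). It held for 12 of 31 mitotic genes, or 14 adjusted over the list alone (adjusted p = 2.6e-09, and 0.0314 with an estimated correlation), and for 8 of 18 cholesterol genes, or 9 adjusted over the list alone (adjusted p = 8.48e-07, and 0.0307 with an estimated correlation). Of 46 ribosomal protein genes 37 had a negative interaction as deposited (median -0.99, adjusted p = 1.34e-39, and 0.0469 with an estimated correlation), whereas under quantile normalization 2 did, 3 had a positive one and the median was 0.03. Of 24 unfolded protein response genes 8 had a positive and 0 a negative interaction, or 11 and 3 adjusted over the list alone (adjusted p = 0.00184, and adjusted p = 0.0795 with an estimated correlation). In all, 884 probe sets were called, 518 positive and 366 negative. Positive calls made up 58.6%, or 52.2% under cyclic loess normalization and 74.7% without the brightest 5% of probe sets, and the median over all probe sets was 0.16 as deposited and -0.00461 under quantile normalization. The count dropped to 484 and 468 without CD32 2 h replicate 1 and CD32 2 h replicate 2, to 568 and 586 without CD32 6 h replicate 1 and CD32 6 h replicate 2, and to 505 and 481 without CD64 6 h replicate 1 and CD64 6 h replicate 2. It dropped to 573 under quantile normalization, 483 of them called as deposited too, and to 417 without the variance trend.

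The cross-linked receptors were themselves measured. FCGR2B, an inhibitory CD32 gene, rose from 424 ± 18.7 (SD, n = 2) to 657 ± 8.98 after 2 h of CD32 (1.55-fold, adjusted p = 0.0059), to 836 ± 90.4 after 6 h of CD32 (1.97-fold, adjusted p = 0.000285) and to 977 ± 54.2 after 6 h of CD64 (2.3-fold, adjusted p = 6.88e-05). After 2 h of CD64 it was 469 ± 9.05 and not called (adjusted p = 0.514). FCGR2A, an activating CD32 gene, was not called in any of the 4 comparisons with control, with signals of 667, 658, 700, 606 and 639 in control, CD32 2 h, CD32 6 h, CD64 2 h and CD64 6 h and adjusted p-values of 0.955, 0.777, 0.559 and 0.829. FCGR3B was not called either (adjusted p = 0.957, 0.444, 0.912 and 0.925). The only probe set for FCGR1A, which encodes CD64, also carries the symbols of 2 pseudogenes. Its signal was 1590 ± 187 (SD, n = 2) in control, 2229 ± 71.3 and 1896 ± 87.2 after 2 h and 6 h of CD32, and 1231 ± 35.9 and 1919 ± 160 after 2 h and 6 h of CD64, and at 2 h it was 1.81-fold lower after CD64 than after CD32 (adjusted p = 0.000505). Against control limma called it 1.41-fold higher after 2 h of CD32 (adjusted p = 0.00919) and 1.29-fold lower after 2 h of CD64 (adjusted p = 0.0393). Both calls were lost without the variance trend and on leaving out some single arrays, the second for most of them. It was not called against control at 6 h. From 2 h to 6 h of CD64 it rose 1.56-fold (limma adjusted p = 0.0026). Of 22 Fc receptor and signalling genes 2 rose and 2 fell after 2 h of CD32, 3 and 2 after 6 h of CD32, 0 and 3 after 2 h of CD64, and 2 and 5 after 6 h of CD64, where the phosphatase PTPN6 fell 2.2-fold and the adaptor GAB2 2.63-fold.

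In the same order of comparisons with control, 2, 2, 1 and 1 of 5 NADPH oxidase genes rose and 0, 0, 3 and 1 fell, with CYBB up 1.87-fold after 2 h of CD32, 2.37-fold after 6 h of CD32 and 2.46-fold after 6 h of CD64. After 2 h of CD64 CYBB was called 1.55-fold lower (adjusted p = 0.02), a call lost without control replicate 1 (0.139), control replicate 2 (0.0526) or CD64 2 h replicate 2 (0.141). Of 26 lysosomal genes 3, 6, 0 and 5 rose and 1, 3, 6 and 8 fell, and camera did not call the list (adjusted p = 0.714, 0.151, 0.611 and 0.731). The protease CTSD rose 1.91-fold after 6 h of CD32 and fell 1.78-fold after 2 h of CD64. Of 16 liver X receptor targets limma called 0 higher in 4 of 4 comparisons (0, 1, 0 and 1 at an unadjusted p under 0.05) and 1, 2, 4 and 3 lower, and camera did not call the list (adjusted p = 0.539, 0.84, 0.213 and 0.186); after 6 h of CD32 the list median was 0.11 while its mean was -0.04. Of 20 cyclin-dependent kinase inhibitors and p53 targets 4, 4, 4 and 4 rose and 2, 3, 1 and 1 fell, with the death receptor TNFRSF10B up 2.76-fold, 3.34-fold, 2.46-fold and 2.85-fold. Of 22 matrix and coagulation genes 2, 4, 1 and 3 rose and 1, 0, 2 and 0 fell. Of 13 ribosome biogenesis genes 1, 0, 3 and 2 rose and 1, 1, 1 and 1 fell, and under the direct comparison at 2 h 5 were higher after CD64 (adjusted p = 0.00314, and adjusted p = 0.0985 with an estimated correlation). The oxidative stress list after 2 h of CD32 had 5 of 18 genes up and 0 down, with a median of -0.09, a mean of 0.31 and a test pointing up (adjusted p = 0.243).

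Markers of other cell types showed few changes. In the 4 comparisons with control limma called 0 of 12 T cell markers, with 0, 1, 1 and 1 at an unadjusted p under 0.05, and 0 of 9 epithelial and fibroblast markers, with 0, 1, 0 and 0. Among 7 B cell markers FCER2, an IgE receptor also found on monocytes, was called higher after 6 h of CD32 (2.35-fold) and lower after 2 h of CD64 (2.57-fold). Leaving out single arrays ended these calls: the first was lost without either control, either CD32 2 h or either CD32 6 h replicate (highest adjusted p = 0.174), and the second without the same arrays or CD64 2 h replicate 1 (highest adjusted p = 0.188). Among 9 natural killer cell markers NKG7 fell 1.49-fold after 2 h of CD64. Among 8 erythroid and platelet markers the globin HBB rose 2.19-fold after 2 h of CD64, a call that was lost without CD64 2 h replicate 2 (adjusted p = 0.0779). Camera called 0 of these 5 lists in the 4 comparisons at either correlation, the lowest adjusted p being 0.207 (B cell list, 2 h of CD32), with 0 at an unadjusted p under 0.05 at the estimated correlation (lowest 0.286), and fry called 0 (lowest adjusted p = 0.116). Between 2 h and 6 h of CD32 camera called the B cell list higher (median log2 change 0.57, adjusted p = 0.0448, and adjusted p = 0.386 with an estimated correlation), with 0 of its 7 genes called by limma and 2 higher at an unadjusted p under 0.05. That call was lost without control replicate 1 (adjusted p = 0.0558), control replicate 2 (0.0549), CD32 2 h replicate 1 (0.16), CD32 2 h replicate 2 (0.0573) or CD32 6 h replicate 1 (0.245). It was also lost under cyclic loess normalization (adjusted p = 0.0527). Fry did not call the list (adjusted p = 0.402).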

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

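The tests of the spike and 3' to 5' gradient and of 1 scaling factor per array below were chosen after the result was seen, as was cyclic loess normalization, and the other 2 tests on ribosomal protein genes were fixed before. The receptor differences were picked out because limma tested the difference between the receptors, or the difference in their change over time, and called it.

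At 2 h, 1256 probe sets differed between CD64 and CD32, and the count dropped to 699 and 586 without CD32 2 h replicate 1 and replicate 2, and to 690 and 770 without CD64 2 h replicate 1 and replicate 2. The median log2 difference, CD64 minus CD32, was -0.64 for interferon-stimulated genes and 0.50 for mitotic genes. The log2 difference was 3.24 for CXCL8, 2.75 for CXCL2, 2.02 for SEPHS2, an enzyme of selenium metabolism, at least 2.01 for the formin DIAPH3 and 1.99 for the phosphatase PPM1B. It was -2.51 for CX3CR1, -2.44 for TNFAIP6, at most -2.38 for the receptor PILRA, at most -2.26 for the kinase EPHA1 and -2.24 for the vesicle protein VAMP2. The PILRA call was lost without CD32 2 h replicate 1, CD32 2 h replicate 2 or CD64 2 h replicate 1 (highest adjusted p = 0.0759), and the EPHA1 call without any single array outside the CD32 6 h group (highest adjusted p = 0.22).

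At 6 h, 1357 probe sets differed, and the count dropped to 749 without CD32 6 h replicate 1 and to 646 and 705 without CD64 6 h replicate 1 and replicate 2. The median log2 difference was -0.95 for immediate early genes, -0.83 for cholesterol genes and -0.43 for glycolysis genes. The log2 difference was 3.06 for IFIT1, 2.67 for the fatty acid receptor FFAR2, 2.35 for the kinase CAMKK2, 2.33 for RIGI and 2.28 for CASP6. It was at most -4.07 for FOSB, at most -3.02 for the transcription factor MEF2D, at most -2.81 for the chaperone FKBP8, -2.75 for EGR1 and -2.61 for RGS1, a regulator of G protein signalling. The FFAR2 call was lost without CD64 6 h replicate 1 (adjusted p = 0.0516), the CAMKK2 call without CD64 6 h replicate 2 (adjusted p = 0.078), and the RGS1 call without CD32 6 h replicate 2 (adjusted p = 0.0611) or CD64 6 h replicate 2 (adjusted p = 0.0565).

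The change from 2 h to 6 h differed between the receptors for 884 probe sets; the count dropped to 484 and 468 without CD32 2 h replicate 1 and replicate 2, to 568 and 586 without CD32 6 h replicate 1 and replicate 2, and to 505 and 481 without CD64 6 h replicate 1 and replicate 2. The median interaction was -0.61 for immediate early genes, 0.57 for interferon-stimulated genes, -0.60 for cholesterol genes, -0.72 for glycolysis genes and -0.45 for mitotic genes. For ribosomal protein genes it was -0.99 as deposited and 0.03 under quantile normalization. The interaction was 4.49 for IFIT1, 3.997 for TNFAIP6, 3.70 for CX3CR1, 3.66 for IFIT5 and 3.54 for RIGI. It was at most -3.83 for FOSB, -3.52 for CXCL8, -3.14 for HMGCS1, -3.01 for EGR1 and -2.66 for RGS1. The RGS1 interaction was called without CD64 2 h replicate 1 and lost without any other single array (highest adjusted p = 0.142).

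Control probe sets, which the comparisons leave out, stood above the control arrays in several groups. Bacterial transcript signal was 1.72 log2 units higher in CD32 6 h than in control, and its mean log2 signal was 11.48 in CD32 2 h and 11.18 in CD64 2 h against 10.88 in control. The middle probe set of 28S ribosomal RNA had a mean signal of 4146 ± 19.8 (SD, n = 2) in CD64 6 h, 1118 ± 41.7 in CD32 2 h, 1323 ± 12.7 in CD32 6 h and 383 ± 131 in CD64 2 h against 742 ± 75.9 in control.

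Ribosomal protein genes were lower after 6 h of CD64 than in control, with a median of -0.61 over 46 genes as deposited, 38 of them called by limma, or 10 under cyclic loess. A single scaling factor per array would move all genes alike and could not set the list apart from the others. The list median minus the median of all genes was -0.568 (95% bootstrap interval over the 46 genes, not over arrays, -0.625 to -0.51). That difference was known when the test was chosen, so the test restates the call of the list and adds no support. Under quantile normalization the list median lay 0.00864 from the median of all genes, but 96 equally bright probe sets of other genes had a median of -0.071 there, so that test does not separate the list from a difference tied to brightness. Compression of bright signals on the CD64 6 h arrays was tested with 10000 sets of other genes of equal control signal, of which 99.2% had a median as low (matched median -0.66, 95% range -0.71 to -0.62), and the ribosomal median lay above that range, so neither prediction was met. Other genes of equal control signal fell at least as far, so these values show no fall particular to ribosomal protein genes. A difference between arrays tied to brightness and a biological fall shared with other bright genes both remain open.

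Immediate early and cholesterol genes were higher after 6 h of CD32 than after 6 h of CD64, by a median of 1.44 over the 15 immediate early genes called and 1.39 over the 10 cholesterol genes called. These groups were also 3 log2 units apart in bacterial transcript signal. If a gradient of hybridisation or RNA quality were the cause, the CD64 2 h arrays should be higher in the same genes, by at least 0.378 and 0.366. They lay 1.58 log2 units above CD64 6 h in the same signal. These limits were set below a shift in full proportion to the bacterial transcript signal. The genes were picked for lower signal on the same CD64 6 h arrays, which raises the tested medians. The medians were 0.31 (95% bootstrap interval over genes -0.0691 to 0.672) and 0.269 (-0.272 to 0.458). Both intervals contain the limit and 0 and end below a shift in full proportion. For these 15 and 10 genes a gradient acting in part and a difference between the receptors cannot be told apart. The receptor difference remains open as the biological explanation.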

How the results depend on the processing

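Cyclic loess normalization, leaving out the brightest 5% of probe sets, leaving out both arrays of a 6 h group and setting each receptor against its own control array were chosen after seeing the data. With no floor, double the floor, no filter, the term for duplicate arrays or 1 probe set per gene, each of the 9 counts of called probe sets stayed within 1.5 times its value. Among the called named genes, quantile normalization ended 51 calls and turned 3 directions, cyclic loess ended 35 calls, fitting without the variance trend 118 and testing with no filter 91. Between 20.2% and 29.8% of probe sets per array lay at or under the floor, so changes of weakly expressed genes are bounded by it. With 2 arrays per group, single arrays decided many calls.

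Without the variance trend, limma called 725 probe sets after 2 h of CD64, 830 between the receptors at 2 h, 54 from 2 h to 6 h of CD32, 579 from 2 h to 6 h of CD64 and 417 in the interaction, 289 were shared by the receptors at 2 h, and camera called 4 lists between the receptors at 6 h. With only the groups compared, 767 were called after 2 h of CD64 and 335 shared at 2 h. Quantile normalization gave 573 in the interaction, and 5 lists after 2 h of CD64 and 7 in the interaction. Cyclic loess gave 5 lists after 2 h of CD64. Without the brightest 5%, 3 lists were called after 2 h of CD64 and 6 in the interaction, where fewer genes stood in each list. Without both CD64 6 h arrays, 222 probe sets changed from 2 h to 6 h of CD32, with fewer arrays behind the variance. With each receptor against its own control array, 257 and 290 probe sets were shared at 2 h and 490 and 493 at 6 h, with 1 control array behind each change. Apart from those fewer genes and arrays, the cause was not tested.

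In the order of the 4 comparisons with control, the 2 receptor differences, the 2 changes over time and the interaction, camera called 10, 12, 8, 11, 11, 8, 12, 11 and 11 of 32 lists at the preset correlation. Not all of these called lists are described above. With an estimated correlation it called 4, 4, 0, 4, 2, 3, 5, 3 and 6, and 8, 9, 6, 9, 8, 6, 8, 11 and 10 were at an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 17, 17, 14, 21, 18, 8, 11, 19 and 12.

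Among the called lists and the called named genes, directions turned under scaling for the ribosomal protein list and for the genes MT2A and CTSG. The median of ribosomal protein genes became -0.12 under quantile normalization after 6 h of CD32, while under cyclic loess it was 0.0566 and the test pointed down. It became -0.0457 under cyclic loess after 2 h of CD64. Under quantile normalization it became 0.12 between the receptors at 6 h, -0.0137 from 2 h to 6 h of CD32 and 0.0298 in the interaction. The log2 change of MT2A became 0.18 from 2 h to 6 h of CD64 and 0.30 in the interaction, and the interaction of CTSG 0.0928, all under quantile normalization. The cause was not tested.

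Leaving out 1 array gave 579 to 1095 calls after 2 h of CD32 (lowest 579 and 592 without the CD32 2 h replicates 1 and 2), 942 to 1437 after 6 h of CD32 (942 without CD32 6 h replicate 1), 642 to 1115 after 2 h of CD64 (642 and 711 without the CD64 2 h replicates, 741 without control replicate 1) and 967 to 1531 after 6 h of CD64 (967 and 1023 without the CD64 6 h replicates). Between the receptors at 2 h it gave 586 to 1287 (699 and 586 without the CD32 2 h replicates 1 and 2, 690 and 770 without the CD64 2 h replicates), and at 6 h 646 to 1358 (749 without CD32 6 h replicate 1, 646 and 705 without the CD64 6 h replicates). From 2 h to 6 h of CD32 it gave 40 to 307 (52 and 40 without the CD32 2 h replicates, 74 and 130 without the CD32 6 h replicates), and from 2 h to 6 h of CD64 455 to 1074 (602 and 568 without the CD64 2 h replicates, 492 and 455 without the CD64 6 h replicates). In the interaction it gave 468 to 888 (484 and 468 without the CD32 2 h replicates, 568 and 586 without the CD32 6 h replicates, 505 and 481 without the CD64 6 h replicates). Shared calls at 2 h ranged from 270 to 463 (336 without control replicate 1, 270 and 293 without the CD32 2 h replicates, 311 and 344 without the CD64 2 h replicates). Camera called 4 to 9 lists after 2 h of CD64 (5 without control replicate 1, 4 without CD64 2 h replicate 2) and 5 to 8 between the receptors at 6 h (5 without CD32 6 h replicate 2). Of the named genes called in the 9 comparisons, 52 of 83, 64 of 82, 53 of 87, 74 of 83, 37 of 63, 34 of 59, 9 of 43, 44 of 58 and 37 of 55 kept their call without any 1 array. An array left out leaves fewer residual degrees of freedom, and no other cause was tested.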

Other observations

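The tests of a later onset in the last paragraph were chosen after the result was seen, and the gene lists were fixed before. After 2 h of CD32, 6 h of CD32, 2 h of CD64 and 6 h of CD64, 1, 1, 3 and 3 of 15 heat shock and chaperone genes rose and 3, 2, 0 and 5 fell by limma, and 1, 1, 3 and 3 rose and 3, 2, 1 and 5 fell adjusted over the list alone; after 2 h of CD64, 4 were lower at an unadjusted p under 0.05. The list as a whole was not called by camera (adjusted p = 0.268, 0.675, 0.605 and 0.639). The co-chaperone DNAJA1 rose 2.63-fold, 2.32-fold, 2.04-fold and 3.29-fold in the same order. HSP90AA1, the inducible form of HSP90, fell 2.25-fold after 2 h and 3.6-fold after 6 h of CD32. DNAJB1 fell 1.52-fold and 1.58-fold after 2 h and 6 h of CD32 and 2.61-fold after 6 h of CD64, and HSPH1 rose 1.95-fold after 2 h of CD64. The list median was -0.20 after 2 h of CD64, where the mean was 0.05 and the test pointed up, and 0.06 after 6 h of CD64 (-0.02 under quantile normalization), where the mean was -0.05 and the test pointed down.

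Of 17 regulators of apoptosis limma called 4, 4, 4 and 5 higher and 1, 1, 1 and 2 lower in the same order. Adjusted over the list alone, 6, 4, 4 and 5 were higher and 2, 1, 1 and 2 lower. Camera did not call the list (adjusted p = 0.539, 0.23, 0.258 and 0.0901). PMAIP1, which promotes apoptosis, rose 2.3-fold, 2.59-fold, 2.04-fold and 4.19-fold. The survival factor MCL1 rose 2.33-fold after 6 h of CD32 and 2.81-fold after 2 h of CD64, and BIRC2, an inhibitor of apoptosis, 1.88-fold after 2 h of CD32 and 2.24-fold after 6 h of CD64. BCL2A1 fell 1.88-fold after 2 h of CD32. The list median was -0.06 after 2 h of CD32, where the mean was 0.02, and -0.22 after 2 h of CD64 (0.06 under quantile normalization), where the mean was 0.02. Of 9 histone genes 1, 1, 1 and 1 rose and 2, 1, 1 and 3 fell (adjusted p = 0.205, 0.489, 0.66 and 0.206). The linker histone H1-10 fell 2.33-fold after 2 h of CD32, 2.04-fold after 2 h of CD64 and 3.01-fold after 6 h of CD64, and H2BC12 rose 1.6-fold, 1.52-fold, 1.48-fold and 2.09-fold. The median of DNA replication genes after 2 h of CD64 was -0.03, where the mean was 0.06 and the test pointed up.

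A hypothesis is that part of the changes seen at 2 h of CD32 may begin later after CD64, although 518 of the 1192 probe sets called after 2 h of CD32 were already called the same way after 2 h of CD64, which goes against it for these, and 37 the opposite way. Of the 1192, 71.9% went the same way from 2 h to 6 h of CD64 (r = 0.508, across probe sets, which are not independent replicates), with 385 called the same way and 48 the opposite way against 83.5 and 81.2 if the calls were independent. The relation held without the interferon list (r = 0.515), and the mirror comparison, the 1224 probe sets called after 2 h of CD64 against the change from 2 h to 6 h of CD32, gave r = -0.0431 and 46.2%. Bacterial transcript signal was higher by 0.59 in the first comparison and fell by 1.58 in the second. A gradient following it alone would give r below 0, whereas r was above 0 (95% bootstrap interval over probe sets 0.463 to 0.554). That r was known when the test was chosen, so the test restates it and adds no support. It cannot exclude a gradient acting beside another difference. Without the brightest 5% r was 0.501 over 1097 probe sets. Most of the 1192 stay in, so this does not decide on compressed bright signals. The middle probe set of 28S ribosomal RNA rose in both comparisons, from 742 to 1118 and from 383 to 4146. That of 18S ribosomal RNA fell in both, at signals near the floor. It went from 95.6 and 113.6 in control to 29.2 and 52.8 in CD32 2 h. From CD64 2 h to CD64 6 h it went from 83.2 and 60.2 to 44.5 and 27.6. A difference between arrays that goes with the 28S signal remains open beside a later onset.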
